A study of Homo sapiens with 6 samples.

How the data were processed

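RNA from the human pancreatic cancer cell line ASPC-1 was sequenced in 6 libraries, 3 from cells in medium of pH 7.4 and 3 from cells in medium of pH 6.4. Per the labels' protocols, ribosomal RNA was removed with a kit, the RNA was broken into short fragments, cDNA was primed with random hexamers and the libraries were sequenced as paired ends on an Illumina HiSeq instrument. The molecule label reads polyA RNA instead, which conflicts with that protocol. Transcripts of replication-dependent histone genes, which mostly lack a poly(A) tail, were measured with many reads, but this does not settle the conflict. Whether the counting used strand is not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. The aligner, the counting tool and the genome build are likewise not given in the sources used here.

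The analysis used a heat map table and a table of the authors' comparison of the groups. The heat map table deposited by the authors holds a score for each of 495 genes in each library, a z-score for which the authors centred and scaled every gene over the 6 libraries. These are the genes with an unadjusted p under 0.05 and more than a 2-fold change in the comparison table. The comparison table lists 16761 genes with a normalised signal for each group, which per the file headers is the mean of the group's libraries after division by size factors. It also gives the fold of the acid group over the other, its log2 fold change, and a p-value with its adjusted p-value, all computed by the authors. The submitters named DESeq for this test in their processing notes, with no version. The gene length and coordinates in this table are also the authors' values. The coordinates were compared with GENCODE 29 on GRCh38, in which 16579 of the gene identifiers were found, 100.0% of them on the same chromosome and 96.0% with a start within 1 kb. Of these, 99.7% were annotated as protein coding.

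No table of read counts per library was used, but the group means in the comparison table are printed with enough digits to recover the reads behind them. A group mean is the sum of 3 whole numbers, each divided by its library's size factor and by 3. The steps of genes with a single read gave the size factors, and for each gene all combinations of whole reads were searched for sums that matched the printed mean. Means above 5000 were searched with each library between 0.5 and 1.6 times the group mean, and means above 20000 were not searched. Exactly 1 combination was found in both groups for 16637 genes (99.3%), and no searched gene was left without a solution. The other 124 genes, all with an authors' mean of 15525 or more in a group, were not recovered. They carry 15.7% of the summed means and are described only with the authors' deposited values. The library behind each position was fixed by the heat map, whose columns carry the group and the replicate number. For 492 recovered genes, z-scores computed from the recovered reads were compared with the 2952 values in the heat map, with a median difference of 1.4e-15 and a largest difference of 1.3e-14. The next best of the 36 orders of libraries gave a median difference of 0.039. The recovered reads are therefore derived values. In each of 2 simulations of 3640 genes in 1 group of 3 libraries, all 3640 had a single solution, which was right. The means in these simulations did not reach the upper part of the searched range. Their size factors were further apart than those of pH 6.4 replicates 2 and 3 (0.8945 each), so such cases were not covered. An earlier run with other size factors left some genes with more than 1 solution and none with a wrong single solution.

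The recovered reads summed to 18707645, 24196810 and 23074345 in pH 7.4 replicates 1, 2 and 3, and to 22374820, 18337768 and 18313732 in pH 6.4 replicates 1, 2 and 3. The library totals that gave the z-scores back through FPKM were fitted, and came to about 22200000, 28800000, 27600000, 26600000, 21600000 and 21600000 reads in the same order. Of the recovered genes, between 14827 and 15125 had a read in a library, and the 10 with the most reads held at most 0.92% of the recovered reads. The genes that were not recovered, which include the most abundant ones, are outside this share. With 3 libraries per group and this depth, genes with few reads are measured with the least precision.

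Before the data were examined, the groups, the tests, the alternatives, 31 gene lists and the rule for named genes were fixed. The design assumed a table of counts and a quasi-likelihood count model, with limma-trend as the test for normalised values. The deposited unit differed from those counts, so limma-trend was used. Recovered reads were divided by the authors' size factors, and log2(value + 1) was tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance, for genes with at least 10 reads in at least 3 libraries. Of the recovered genes, 12572 were tested and 4065 fell below this filter. P-values were adjusted by the Benjamini-Hochberg method, genes with an adjusted p under 0.05 were called changed, and a change of at least 2-fold was counted separately. All 6 libraries entered the fit, with no covariate. The tests of genes and of gene lists made here are two-sided. The shares of length-matched random lists, the Poisson p and the permutation p given further below are one-sided. Reads were recovered with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

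The gene lists came from textbook knowledge. They covered cholesterol synthesis, fatty acid synthesis and desaturation, fatty acid oxidation and PPAR targets, glycolysis and lactate, MondoA and ChREBP targets, hypoxia response, pH regulation and proton transport, proton-sensing receptors and channels, vacuolar ATPase, lysosome and autophagy, ATF4 and amino acid stress response, unfolded protein response, heat shock proteins, NRF2 targets, and p53 targets and growth arrest. They also covered mitotic cell cycle, DNA replication, replication-dependent histones, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, NF-kB and inflammatory cytokines, interferon-stimulated genes, epithelial identity, mesenchymal transition and invasion, drug transporters and resistance, metallothioneins and metal response, fibroblast and endothelial markers, and blood and immune cell markers. Some genes stand in more than 1 list. Each list was tested with camera at its preset inter-gene correlation of 0.01, which compares the list with all other tested genes, and adjusted over the 31 lists. Each was also tested with an estimated correlation and with fry, and member counts were adjusted over all tested genes and over the list alone.

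Genes were named by the rule fixed beforehand. It took the 10 largest rises and the 10 largest falls among protein-coding genes with an adjusted p under 0.05, at least a 2-fold change, a mean of at least 10 CPM (counts scaled to a common library total) and no overlap between the groups. It added the 2 members of each list with the smallest adjusted p that rose and the 2 that fell, and every tested member of the lists for pH regulation and for proton sensing. Where a list's count of rises or falls was 5 or fewer, the members outside the rule were named as well, after their values were seen. Some genes taken by this rule are not reported here.

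The alternatives were library totals or trimmed mean of M-values (TMM) scaling in place of the authors' size factors, no filter or a stricter filter of 1 CPM in 3 libraries, limma-voom, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, both libraries nearest the other group left out, the authors' deposited test, camera with an estimated correlation, and an authors' adjusted p under 0.01 for the overlap. TMM scaling, the authors' test and the omission of both nearest libraries were added after the data were seen. On simulated reads with the means and totals of these libraries, 200 genes were changed, and 12485 genes passed the filter and were tested, 12287 of them unchanged. The test found 44.0% of genes changed by 1.2-fold, 80.0% of those changed by 1.5-fold, 86.0% of those changed by 2-fold and 98.0% of those changed by 4-fold, with 50 genes of each size. It called 8 of the unchanged genes. The simulated spread was smoothed over genes of similar mean, and no difference between replicates was shared by genes. These rates therefore need not hold for the real libraries. For 31 simulated lists of 20 genes, camera called the list shifted by 1.5-fold and 0 of the 30 unchanged ones. The simulated genes were drawn independently of each other, so this run cannot show how often camera calls unchanged lists of correlated genes.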

Results

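Gene expression was measured by RNA sequencing in ASPC-1, an established human pancreatic cancer cell line, kept in medium of pH 7.4 or in acidified medium of pH 6.4. Each group had 3 replicates, which gave 6 libraries. How long the cells were kept at each pH is not given in the labels. The labels number the replicates without saying whether they were separate cultures, so p-values measure the spread between these samples, which may be technical. Expression is given as normalised reads per gene, the whole reads recovered from the group means that the authors deposited, divided by the authors' size factors. For 16637 genes the recovered reads summed to between 18313732 and 24196810 per library. Library totals that gave back the scores of the authors' heat map ranged from about 21600000 to 28800000 reads. Another 124 genes with the highest means could not be recovered per library, and for these the values of the authors' deposited table are given, with no error of their own. Values are means ± SD over 3 libraries per group. Folds compare group means of log2(value + 1), so they can lie above or below the ratio of the printed means. The added 1 by itself lowers the fold of genes with few reads.

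The comparison asked how gene expression in these cells differed between an acidic medium, used to model the surroundings of a tumour, and medium of physiological pH. At pH 6.4, 21 of the 22 tested genes of the ATF4 and amino acid stress response fell and 0 rose, among them ASNS, which makes asparagine and went from 1068 ± 106 to 342 ± 23.6 normalised reads (SD, n = 3 in each group, a 3.11-fold fall). Transcripts of replication-dependent histones fell for 20 of 25 genes and those of cytosolic ribosomal proteins for 14 of 22, while 8 of 10 mitochondrially encoded transcripts rose. Among genes that handle acid and bicarbonate, CA9, a carbonic anhydrase of the cell surface, went from 147 ± 26.2 to 27.3 ± 15.4 normalised reads, and SLC4A7, a sodium bicarbonate cotransporter, went from 4471 ± 318 to 7482 ± 881. Of 12572 genes tested with limma-trend, 3897 (31.0%) changed at an adjusted p under 0.05, 1886 higher and 2011 lower at pH 6.4. At least a 2-fold change was found for 410 of them, 136 higher and 274 lower. Most changes were smaller, with 89.5% of the changed genes under 2-fold and a median fold, in either direction, of 1.32. The 3 libraries of a group lay on one side of all libraries of the other group for 5912 genes, which is 47.0% of those tested, where chance gives 10%. The count of 3897 became 2300 without pH 7.4 replicate 1, 2235 without pH 7.4 replicate 3, 2407 without pH 6.4 replicate 2 and 2118 without pH 6.4 replicate 3. With library totals as scaling it was 3993, and most of these were higher (2315 higher, 1678 lower). The count of 410 became 269 without pH 7.4 replicate 1, 251 without pH 6.4 replicate 2 and 622 without pH 6.4 replicate 1, and 727 without both libraries nearest the other group. It was 310 with a stricter filter on low reads (85 higher, 225 lower) and 537 with no filter (217 higher, 320 lower).

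The first principal component carried 68.7% of the variance over tested genes and placed the pH 7.4 libraries at -32.9, -13.9 and -25.1 and the pH 6.4 libraries at 9.01, 36.2 and 26.7. The libraries nearest the other group were pH 7.4 replicate 2 and pH 6.4 replicate 1. On an axis with 0 at the mean of the other pH 7.4 libraries and 1 at the mean of the other pH 6.4 libraries, these stood at 0.321 and 0.569. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom from 4.61 to 14.2, so none was a second copy of another. Without both of these libraries, 4997 genes passed the test and 3666 of them were among the 3897. They were chosen because they lay nearest the other group, which favours larger differences once they are left out. Calls of genes or lists gained without either or both of them are therefore no added evidence.

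Positions are those of the authors' deposited table, which match GRCh38. The 10 largest falls that met the naming rule included a trio of genes that respond to stress and act on growth signalling. SESN2, a sestrin that restrains the mTORC1 kinase (ENSG00000130766, chromosome 1 from 28259518 to 28282491, plus strand), went from 3851 ± 806 to 788 ± 91.8 normalised reads (log2 fold change -2.27, SE 0.15, adjusted p = 0.000174). DDIT4, another inhibitor of mTORC1 signalling (ENSG00000168209, chromosome 10 from 72273919 to 72276036, plus strand), went from 3156 ± 669.7 to 663 ± 29.1 (adjusted p = 0.000151). TRIB3, a pseudokinase gene induced by ATF4 (ENSG00000101255, chromosome 20 from 362835 to 397559, plus strand), went from 4972 ± 1055 to 1268 ± 61.1 (adjusted p = 0.000237). The sterol efflux transporters fell as well, with ABCA1 (ENSG00000165029, chromosome 9 from 104781006 to 104928155, minus strand) going from 508 ± 130.5 to 123 ± 19.7 (adjusted p = 0.000306) and ABCG1 falling 4.28-fold. CCL24, a chemokine for eosinophils (ENSG00000106178, chromosome 7 from 75810825 to 75823356, minus strand), went from 499 ± 47.2 to 111 ± 23.8 (adjusted p = 2.38e-05). The remaining falls were those of LGALS4, a lectin of digestive epithelium (5.99-fold), GPA33, an antigen of intestinal epithelium (4.76-fold), GRAMD1B, a sterol transfer protein (4.44-fold), and NPNT, a matrix protein (3.95-fold). The calls of LGALS4, GPA33, GRAMD1B and NPNT were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3 or with no filter on low reads (adjusted p from 0.0501 to 0.123).

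The largest rise that met the naming rule was that of ITGBL1, an integrin beta-like protein (ENSG00000198542, chromosome 13 from 101452593 to 101720856, plus strand), which went from 146 ± 32.0 to 473 ± 126 normalised reads (log2 fold change 1.68, SE 0.22, adjusted p = 0.00127). ADAM19, a membrane metalloprotease, went from 147 ± 21.8 to 420.0 ± 90.9 (adjusted p = 0.000214), and RGS4, a regulator of G protein signalling, went from 1444 ± 388 to 3720.2 ± 368 (adjusted p = 0.00365). GAD1, which makes GABA from glutamate, rose 2.52-fold. Further rises were those of NMNAT2 (2.57-fold), MAST4 (2.45-fold), TTN (2.40-fold), NEK10 (2.29-fold) and CDYL2 (2.28-fold). In all, 115 genes met the rule before the largest were taken, 24 higher and 91 lower. The call of NMNAT2 was lost without pH 7.4 replicate 1 or 3 or pH 6.4 replicate 2 or 3, or with no filter on low reads or with limma-voom (adjusted p from 0.0544 to 0.144).

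Genes for pH regulation and proton transport went both ways, with 4 of 19 tested genes higher, 7 lower and 8 not past the test. With adjustment over this list alone, 4 rose and 8 fell (camera adjusted p = 0.191). The falls were led by the monocarboxylate carrier SLC16A4, which went from 3323 ± 303 to 1798 ± 190.0 normalised reads (adjusted p = 0.000108), and by CA9, which fell 5.75-fold (adjusted p = 0.00206). The other falls were SLC4A2 (1.20-fold), BSG (1.26-fold), SLC4A4 (4.93-fold), CA13 (1.18-fold) and SLC9A3 (2.33-fold), which include the anion exchanger SLC4A2 and BSG, a chaperone of lactate carriers. SLC4A7 rose 1.67-fold (adjusted p = 0.000355). The other rises were SLC16A3 (1.23-fold) and SLC9A7 (1.47-fold) and SLC4A8, which had few reads (from 2.23 ± 1.38 to 12.4 ± 2.85). The lactate carrier SLC16A1 had a log2 fold change of -0.05 (adjusted p = 0.533). SLC9A2, SLC4A5, SLC4A11, CA2 and CA12 did not pass the test either, though CA12 passed with the replicate number as a block. The calls of SLC4A4, CA13, SLC9A3, SLC16A3 and SLC9A7 were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3, with no filter on low reads or without both libraries nearest the other group (adjusted p from 0.0503 to 0.152).

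Of the 10 proton-sensing receptors and channels tested, 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.450). PACC1, a proton-activated chloride channel, rose 1.53-fold (adjusted p = 0.000776). The potassium channel genes KCNK1 and KCNK5 rose 1.21-fold and fell 1.38-fold. GPR132, ASIC1, ASIC3, TRPV1, TRPM7, KCNK6 and P2RX4 did not pass. Of 18 vacuolar ATPase genes, which encode the pump that acidifies lysosomes, ATP6V0A2 rose (1.17-fold) and ATP6V0A1 (1.35-fold) and ATP6AP1 (1.22-fold) fell. When adjusted over the list alone, 0 rose and 1 fell (camera adjusted p = 0.350). Among 27 lysosome and autophagy genes, 3 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.340). The rises were CTSL (1.28-fold), GLA (1.29-fold) and CTSZ (1.20-fold), and the falls were MAP1LC3B (1.53-fold), CTSD (1.40-fold), ULK1 (1.27-fold), PSAP (1.19-fold) and TFEB (1.36-fold), where MAP1LC3B encodes an autophagosome protein and TFEB a regulator of lysosomal genes. The calls of KCNK1, ATP6V0A2, ATP6AP1, CTSZ, ULK1, PSAP and TFEB were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3 or with library totals as scaling (adjusted p from 0.0532 to 0.151).

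The ATF4 list, which holds targets and partners of a transcription factor induced by amino acid shortage, had a median log2 fold change of -0.77 (camera adjusted p = 2.63e-18, and adjusted p = 0.585 with an estimated correlation). Adjusted over the list alone, 21 genes fell and 0 rose. ASNS fell 3.11-fold (adjusted p = 5.99e-06), and AARS1, the alanyl-tRNA synthetase, fell 1.70-fold (adjusted p = 4.01e-05). Transcripts of ATF4 itself went from 10263 ± 1008 to 7082 ± 385 normalised reads (adjusted p = 0.000523), a fall of 1.45-fold, and CHAC1, which degrades glutathione, fell 3.68-fold. STC2, the single tested member not past the test, had a log2 fold change of -0.82 (adjusted p = 0.126). In the unfolded protein response, 1 of 19 tested genes rose and 9 fell, with a median log2 fold change of -0.14 (camera adjusted p = 0.00778, and adjusted p = 0.585 with an estimated correlation). With adjustment over this list alone, 2 rose and 9 fell. HYOU1 and XBP1, a chaperone of the endoplasmic reticulum and a transcription factor of the response, fell 1.42-fold and 2.44-fold, and HSPA5, the main chaperone of that compartment, went from 14032 ± 1858 to 8940.2 ± 203. CRELD2 was the member that rose (1.43-fold). ATF4, CHAC1, STC2 and HSPA5 were singled out after their values were seen. The call of CRELD2 was lost without pH 6.4 replicate 3 (adjusted p = 0.0540). STC2 passed without pH 6.4 replicate 2 (adjusted p = 0.0493).

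Heat shock proteins moved the other way, with 5 of 11 tested genes higher and 0 lower (camera adjusted p = 0.00525, and adjusted p = 0.585 with an estimated correlation). When adjusted over the list alone, 7 rose and 1 fell. HSPA1A went from 353 ± 43.5 to 606 ± 43.2 normalised reads (adjusted p = 0.000477) and HSPA1B rose 1.65-fold, although these are near-identical copies whose reads the counting could divide between them. DNAJA1, HSPH1 and BAG3, a co-chaperone, rose by 1.26-fold, 1.48-fold and 1.27-fold. In the authors' deposited table, HSPA8 and HSP90AA1 were 1.44-fold and 1.39-fold higher (adjusted p = 1.07e-08 and 0.00550), and HSP90AB1 did not pass. NRF2 targets, which defend against oxidants, had 0 of 15 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.115). They were SLC7A11 (1.39-fold), FTL (1.53-fold), ABCC2 (1.26-fold) and TKT (1.21-fold). Of 3 further members in the authors' deposited table, TXNRD1 was 1.17-fold higher and NQO1 1.29-fold lower (adjusted p = 0.0341 and 0.000699), and FTH1 did not pass. Among 18 p53 targets, 2 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.245). GDF15, a stress-induced cytokine, went from 315 ± 95.9 to 42.9 ± 6.23 (adjusted p = 4.84e-05). The other falls were GADD45A (1.58-fold), TNFRSF10B (1.32-fold), BBC3 (2.17-fold) and CDKN1A (1.27-fold), and the rises were FAS (1.30-fold) and BTG2 (1.72-fold). The calls of FTL, TKT, CDKN1A, FAS and BTG2 were each lost in at least 1 setting, without pH 7.4 replicate 1 or 3 or pH 6.4 replicate 1, 2 or 3 (adjusted p from 0.05001 to 0.104).

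Fatty acid synthesis and desaturation had 6 of 13 tested genes lower and 1 higher (camera adjusted p = 0.0189, and adjusted p = 0.585 with an estimated correlation). Adjusted over the list alone, 1 rose and 8 fell. SCD, the stearoyl-CoA desaturase, went from 11714 ± 2487 to 4444 ± 577 normalised reads (adjusted p = 0.00457), and SREBF1, which encodes the transcription factor of this pathway, fell 2.40-fold. FADS2 and ACLY fell 1.66-fold and 1.25-fold, and ELOVL6, an elongase, rose 1.38-fold. SCD and SREBF1 were singled out after their values were seen. Cholesterol synthesis genes divided evenly, 4 higher and 4 lower of 24, as they did adjusted over the list alone (camera adjusted p = 0.857). The median log2 fold change of this list lay below 0 (-0.0005) and its mean above (0.0008). The rises included SQLE (1.52-fold), HMGCS1 (1.31-fold) and NSDHL (1.24-fold), and the falls included DHCR7 (1.32-fold), TM7SF2 (1.74-fold) and PMVK (1.37-fold). In fatty acid oxidation, 1 of 14 tested genes rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.149). PDK4 rose 1.44-fold, and CREB3L3 (1.79-fold), ETFDH (1.31-fold) and HADHA (1.15-fold) were among the falls. The calls of SQLE, HMGCS1, NSDHL, PMVK, PDK4 and HADHA were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3, with library totals as scaling, with no filter on low reads or without both libraries nearest the other group (adjusted p from 0.0513 to 0.167).

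Glycolysis genes showed no common direction (camera adjusted p = 0.954), with 4 of 17 higher, 5 lower and 8 not past the test. With adjustment over this list alone, 4 rose and 6 fell. The rises were ENO2 (1.72-fold), HK1 (1.32-fold), PFKFB3 (1.29-fold) and ALDOC (1.39-fold). The falls were PDK1 (1.40-fold), HK2 (1.28-fold), SLC2A1 (1.90-fold), TPI1 (1.14-fold) and PFKL (1.17-fold), where SLC2A1 encodes the glucose transporter GLUT1. In the authors' deposited table, PKM and ENO1 were 1.23-fold and 1.17-fold lower (adjusted p = 0.00276 and 0.0315), while GAPDH and LDHA did not pass. Of the 6 MondoA and ChREBP targets, which respond to glucose phosphates, PFKFB3 (1.29-fold) and KLF10 (1.22-fold) rose and ARRDC3 (1.67-fold) and MLXIPL (2.70-fold) fell. When adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.218). TXNIP, a member that did not pass, went from 17019 ± 5298 to 6085 ± 2963 normalised reads (adjusted p = 0.0678), and in the authors' deposited table it was called (adjusted p = 0.0158). In the hypoxia response, 1 of 17 tested genes rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0637). P4HA2, a collagen prolyl hydroxylase, rose 1.78-fold, and VEGFA, the angiogenic growth factor, fell 1.88-fold. The other falls were DDIT4, PDK1, NDRG1, CA9 and SLC2A1, so DDIT4, PDK1, CA9 and SLC2A1 each count in another list too. The hypoxia list passed without pH 7.4 replicate 1 (adjusted p = 0.0424), pH 7.4 replicate 2 (adjusted p = 0.0444) or pH 6.4 replicate 2 (adjusted p = 0.0117), with library totals as scaling (adjusted p = 0.0451), with no filter on low reads (adjusted p = 0.0495) and without both libraries nearest the other group (adjusted p = 0.0431). It also passed with the replicate number as a block. The calls of ALDOC, TPI1, PFKL, KLF10 and MLXIPL were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3 or with library totals as scaling (adjusted p from 0.0515 to 0.128). TXNIP passed without pH 6.4 replicate 1, and without both libraries nearest the other group (adjusted p from 7.04e-09 to 0.0189).

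**Figure D1:**
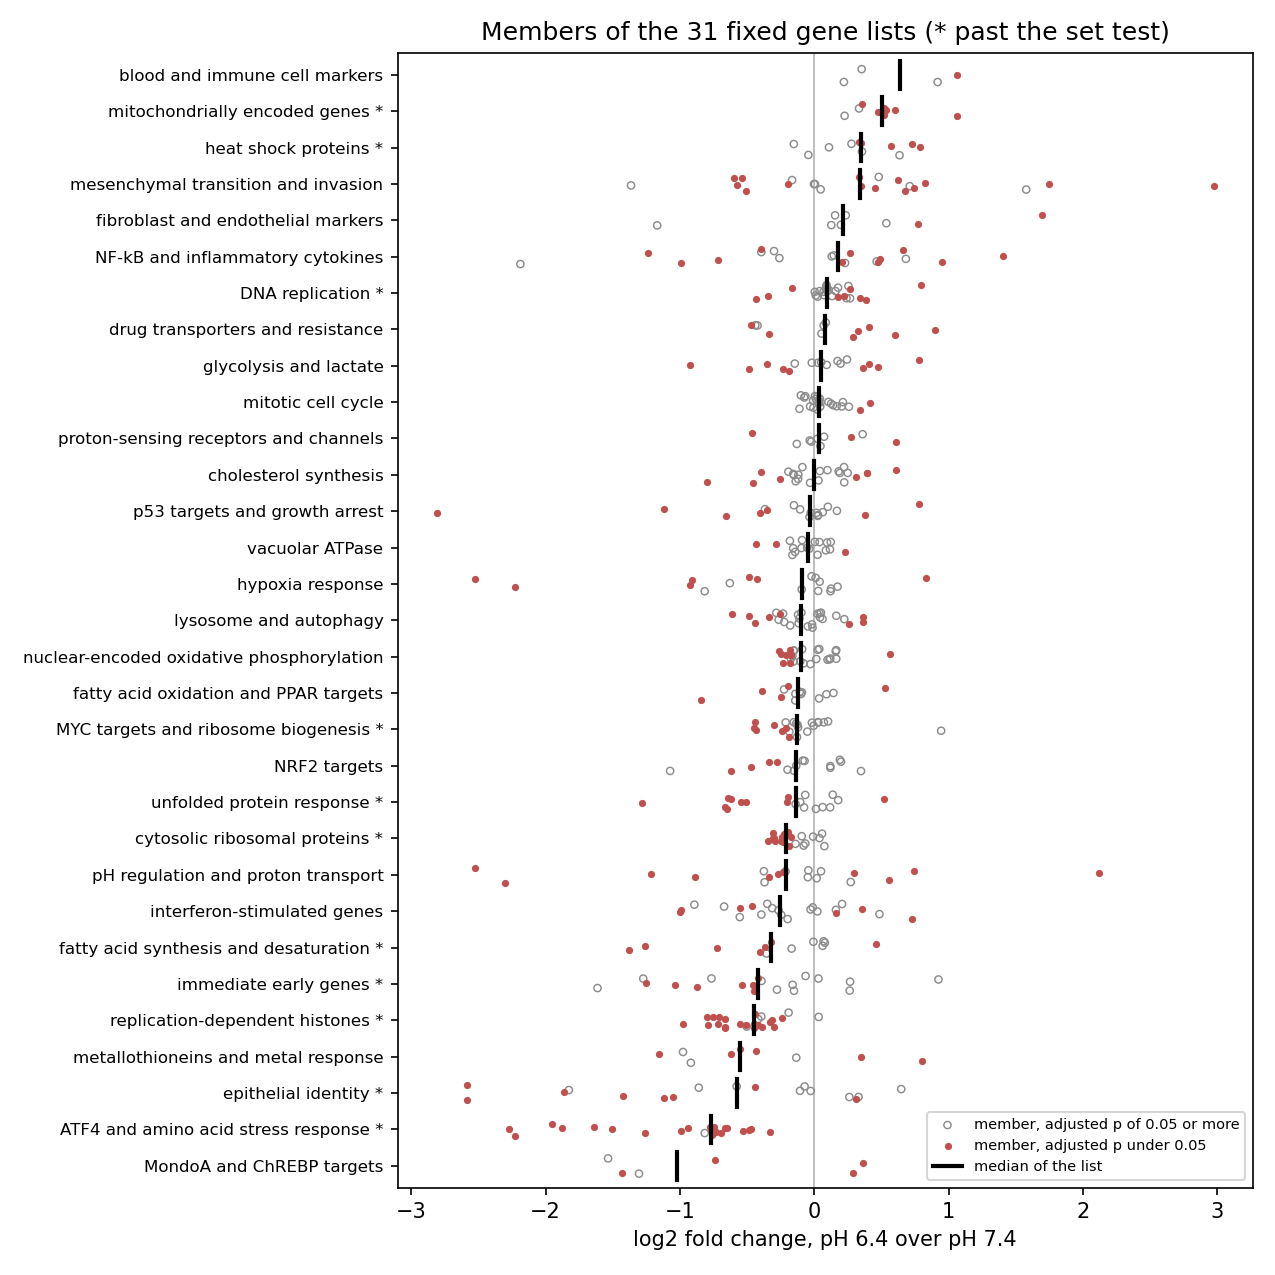
Changes of members in the 31 gene lists between pH 6.4 and pH 7.4. Each row is a list, each point a tested member placed by its log2 fold change (pH 6.4 over pH 7.4), filled where its adjusted p was under 0.05, and the bar is the list's median, from -1.02 for MondoA and ChREBP targets to 0.63 for blood and immune cell markers. Stars mark the 11 lists past camera with its preset correlation, none of which passed with an estimated correlation.

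Replication-dependent histone genes, whose transcripts mostly carry no poly(A) tail and accumulate in S phase, had a median log2 fold change of -0.45 (camera adjusted p = 9.07e-11, and adjusted p = 0.585 with an estimated correlation). Of 25 tested, 20 fell and 0 rose, and 24 fell adjusted over the list alone. H2BC4 went from 7891 ± 672 to 4981 ± 373 normalised reads (adjusted p = 0.000174) and H2AC6 fell 1.97-fold (adjusted p = 0.000108), although close copies of these genes could share reads. The DNA replication list moved slightly upwards, with a median log2 fold change of 0.10 (0.07 to 0.16 over all settings), 6 of 27 genes higher and 3 lower (camera adjusted p = 0.0245, and adjusted p = 0.644 with an estimated correlation). Adjusted over the list alone, 8 rose and 3 fell. CCNE2 (cyclin E2) rose 1.73-fold and GINS1 rose 1.31-fold, while E2F2 and RRM2 fell 1.35-fold and 1.12-fold. This list no longer passed without pH 7.4 replicate 1 (adjusted p = 0.151), pH 7.4 replicate 3 (adjusted p = 0.0878), pH 6.4 replicate 1 (adjusted p = 0.0636) or pH 6.4 replicate 3 (adjusted p = 0.0610). Of 24 mitotic genes, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.191), and the 2 were the checkpoint kinase genes BUB1 (1.33-fold) and BUB1B (1.26-fold). The mitotic list passed without pH 7.4 replicate 2 (adjusted p = 0.0141), and with pH 6.4 replicate 1 left out as well (adjusted p = 0.0246). The call of RRM2 was lost without pH 7.4 replicate 2 or 3 or pH 6.4 replicate 2 or 3, or with library totals as scaling, with no filter on low reads or without both libraries nearest the other group (adjusted p from 0.0554 to 0.167).

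Cytosolic ribosomal protein genes fell by small amounts, 14 of 22 lower and 0 higher, with a median log2 fold change of -0.21 (camera adjusted p = 0.000425, and adjusted p = 0.585 with an estimated correlation). The counts were the same adjusted over the list alone. RPL10A went from 6584 ± 299 to 5180.3 ± 154 normalised reads (adjusted p = 0.00139) and RPL35 fell 1.24-fold, though processed pseudogenes could take reads from such genes. In the authors' deposited table, RPLP0, RPS2, RPL3 and RPS3 were lower (adjusted p = 0.000183, 0.000561, 0.00102 and 0.0223), while RPL4 and RPL7A did not pass. MYC targets and ribosome biogenesis genes had 7 of 22 lower and 0 higher (camera adjusted p = 0.0189, and adjusted p = 0.585 with an estimated correlation), or 8 lower adjusted over the list alone. MYC went from 4857 ± 523 to 3545 ± 118 (adjusted p = 0.00137), and ODC1, of polyamine synthesis, fell 1.36-fold. This list did not pass without pH 7.4 replicate 2 (adjusted p = 0.0810), nor with pH 6.4 replicate 1 left out as well (adjusted p = 0.0944). Mitochondrially encoded genes had 8 of 10 higher and 0 lower, also adjusted over the list alone, with a median log2 fold change of 0.50 (camera adjusted p = 2.97e-06, and adjusted p = 0.585 with an estimated correlation). MT-ATP6 went from 6054 ± 615 to 9172 ± 815 (adjusted p = 0.000802) and MT-ND4L rose 1.43-fold, although neighbouring genes of the mitochondrial genome overlap these. In the authors' deposited table, MT-ND1 was 1.37-fold higher (adjusted p = 7.63e-06), while MT-CO1 and MT-CO3 did not pass. Of 26 nuclear genes for oxidative phosphorylation, SDHA rose 1.48-fold and 7 fell, among them UQCRFS1 (1.20-fold) and ATP5F1C (1.16-fold), with the same counts adjusted over the list alone (camera adjusted p = 0.178). ATP5F1B was 1.19-fold lower in the authors' deposited table (adjusted p = 0.0152). The call of ATP5F1C was lost without pH 7.4 replicate 1 or pH 6.4 replicate 2 or 3 (adjusted p from 0.0697 to 0.0742). It did not pass in the authors' deposited table either (adjusted p = 0.0842).

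Immediate early genes, which answer growth factor and stress signals within minutes, had 7 of 19 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.00612, and adjusted p = 0.585 with an estimated correlation). KLF4, a transcription factor, went from 5508 ± 338 to 4002 ± 123 normalised reads (adjusted p = 0.000471), and DUSP6, a phosphatase that acts on ERK kinases, fell 2.05-fold (adjusted p = 0.00717). MCL1 was 1.28-fold lower in the authors' deposited table (adjusted p = 0.0105). NF-kB targets and inflammatory cytokines went both ways, 7 of 20 higher and 4 lower (camera adjusted p = 0.333). With adjustment over this list alone, 7 rose and 5 fell. The median log2 fold change of this list was 0.18 and its mean -0.02, with camera pointing upwards. NFKBIA, the inhibitor of NF-kB, went from 1896 ± 99.4 to 3016 ± 371 (adjusted p = 0.000431) and NFKB2 rose 1.39-fold. The falls were IL1A (1.99-fold), CXCL2 (2.36-fold), LIF (1.32-fold) and CXCL3 (1.64-fold), which all encode secreted cytokines. Among 22 interferon-stimulated genes, 3 rose and 4 fell (camera adjusted p = 0.149). The rises included IRF1 (1.28-fold) and IRF9 (1.66-fold), and the falls were IFIH1 (1.47-fold), IFI6 (2.00-fold), IFIT2 (1.99-fold) and IFIT1 (1.38-fold). When adjusted over the list alone, 3 rose and 6 fell. The interferon list passed without pH 6.4 replicate 1 (adjusted p = 0.0219), and with pH 7.4 replicate 2 left out as well (adjusted p = 0.00852). It also passed with the replicate number as a block. The calls of LIF, CXCL3 and IFIT1 were each lost in at least 1 setting, without pH 7.4 replicate 1 or 3 or pH 6.4 replicate 1, 2 or 3 or with library totals as scaling (adjusted p from 0.05005 to 0.161).

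Epithelial identity genes had 7 of 17 lower and 1 higher (camera adjusted p = 0.0189, and adjusted p = 0.585 with an estimated correlation), with a median log2 fold change of -0.58. This median ran from -0.89 without both libraries nearest the other group to -0.35 without pH 7.4 replicate 1. On the axis between the groups, the changed genes of this list had a median position of -0.996 in pH 7.4 replicate 1, against 0.392 and 0.233 in pH 7.4 replicates 2 and 3. Adjusted over the list alone, 2 rose and 10 fell. CLDN7, a tight junction protein, went from 649 ± 63.1 to 312 ± 40.5 normalised reads (adjusted p = 0.000151), and CEACAM6, an adhesion molecule, fell 6.01-fold (adjusted p = 0.0108). MUC13, a mucin, rose 1.24-fold. CDH1, which encodes E-cadherin and was singled out after its values were seen, went from 917 ± 478 to 263 ± 156 and did not pass (adjusted p = 0.0875). In the authors' deposited table, the keratin genes KRT8 and KRT18 were 2.04-fold and 1.76-fold lower (adjusted p = 5.64e-05 and 0.000113). In the list for mesenchymal transition and invasion, 9 of 22 genes rose and 5 fell (camera adjusted p = 0.129). With adjustment over this list alone, 12 rose and 5 fell. ITGA5, a fibronectin receptor subunit, went from 608 ± 49.8 to 1014 ± 65.8 (adjusted p = 0.000203) and ZEB1, a repressor of epithelial genes, rose 1.54-fold (adjusted p = 0.000696). The falls were TNC (1.49-fold), CCN2 (1.45-fold), SNAI2 (1.51-fold), CCN1 (1.42-fold) and PLAUR (1.14-fold). VIM did not pass in the authors' deposited table. The calls of CEACAM6, MUC13 and PLAUR were each lost in at least 1 setting, without pH 7.4 replicate 1 or 3 or pH 6.4 replicate 2 or 3, with library totals as scaling or with limma-voom (adjusted p from 0.0517 to 0.144). CEACAM6 and PLAUR did not pass in the authors' deposited table either (adjusted p = 0.0831 and 0.118). CDH1 passed without pH 6.4 replicate 1, and without both libraries nearest the other group (adjusted p from 0.0101 to 0.0381). It also passed with the replicate number as a block.

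Markers of other cell types included genes with few reads. Among 8 fibroblast and endothelial markers, VWF (1.71-fold) and DCN (3.23-fold) rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.197), and DCN went from 6.10 ± 1.63 to 22.3 ± 6.77 normalised reads and VWF from 63.7 ± 7.11 to 109 ± 2.13. LUM, the most abundant of them, went from 4521 ± 985 to 5022 ± 1081 and did not pass (adjusted p = 0.657). Of 4 blood and immune cell markers, CSF1R rose 2.09-fold (from 9.52 ± 3.12 to 20.9 ± 5.47) and 0 fell, while adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.191). These rises went in the same direction as those of the mesenchymal list. Among 12 genes of drug transport and resistance, SLC29A1 (1.51-fold), ABCC4 (1.25-fold), ABCC5 (1.33-fold), ABCG2 (1.86-fold) and NT5E (1.22-fold) rose, where SLC29A1 encodes a nucleoside carrier that takes up gemcitabine, and ABCC2 (1.26-fold) and NT5C (1.39-fold) fell. When adjusted over the list alone, 5 rose and 3 fell (camera adjusted p = 0.340). In the metal response, 2 of 9 genes rose and 4 fell (camera adjusted p = 0.149). Adjusted over the list alone, 2 rose and 5 fell. MT2A, a metallothionein, went from 583 ± 14.1 to 1017 ± 48.8 (adjusted p = 7.04e-05) and MT1E rose 1.27-fold, while SLC30A1 (1.46-fold), TFRC (1.35-fold), SLC40A1 (2.23-fold) and FTL (1.53-fold) fell. Metallothionein genes are close copies that could share reads. The calls of CSF1R, ABCG2, NT5E, NT5C and FTL were each lost in at least 1 setting, without pH 7.4 replicate 1, 2 or 3 or pH 6.4 replicate 2 or 3 (adjusted p from 0.0503 to 0.146).

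**Figure D2:**
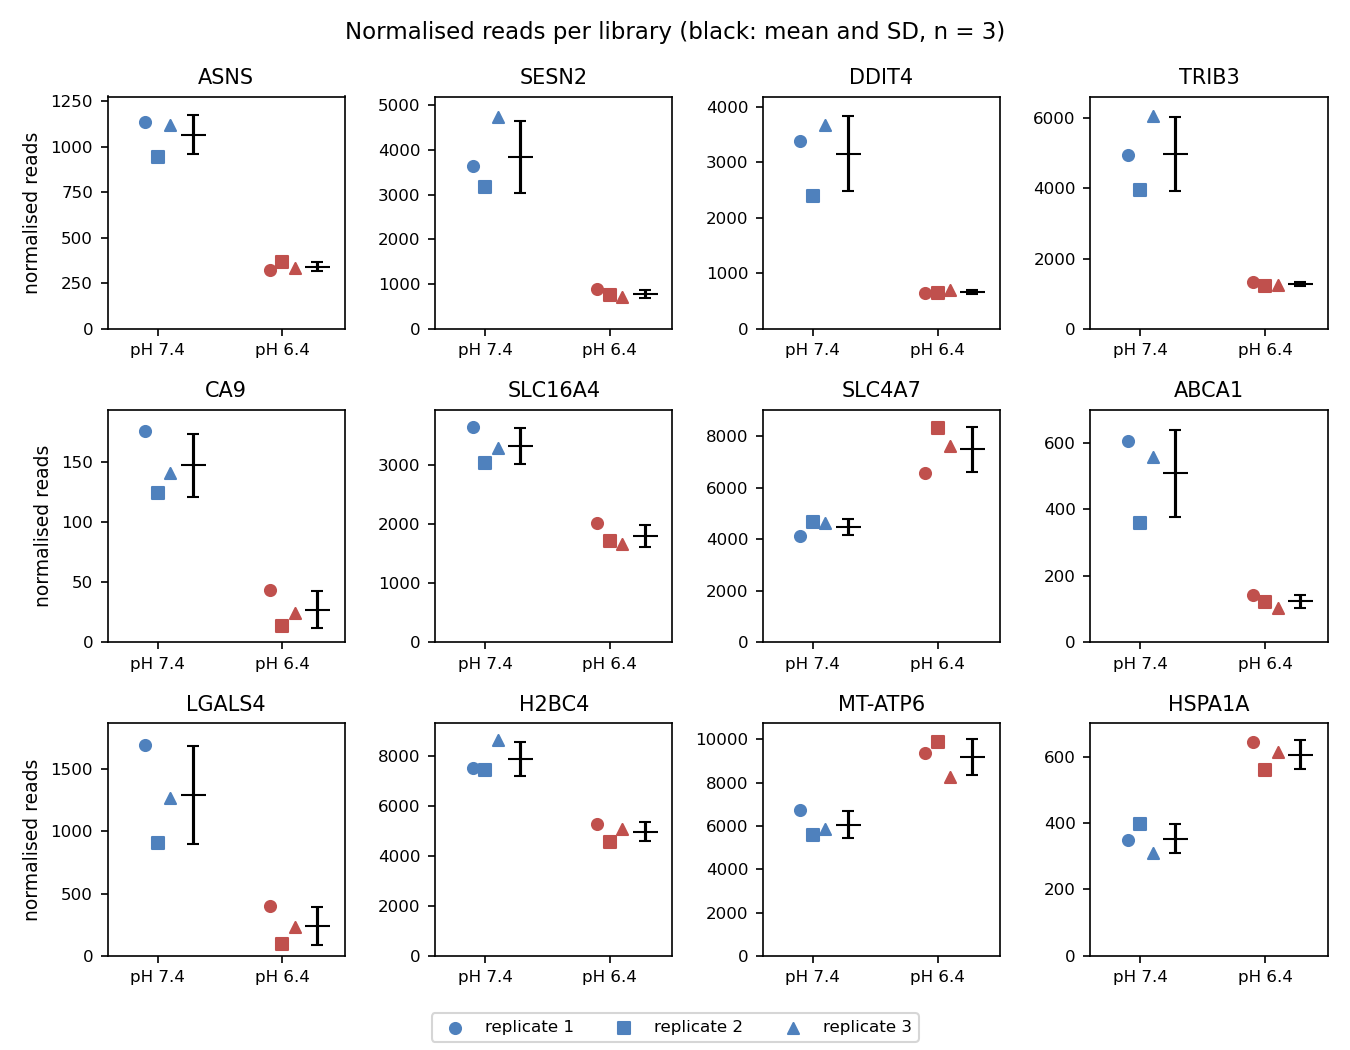
Normalised reads of 12 genes in each of the 6 libraries, on linear axes that start at 0, with a symbol for each replicate and the mean and SD of the 3 libraries of a group in black. No group overlaps the other in any of these genes, and ASNS, for example, has means of 1068 at pH 7.4 and 342 at pH 6.4.

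Of the 31 gene lists, 11 passed camera with its preset correlation, 3 higher and 8 lower, and 0 passed with an estimated correlation, where 11 passed fry and 30 passed its mixed form. The fry test asks whether the genes of a list move together and does not compare them with other genes. Of the 11 lists past camera, 4 did not pass fry, namely DNA replication (adjusted p = 0.236), MYC targets (adjusted p = 0.0623), immediate early genes (adjusted p = 0.122) and epithelial identity (adjusted p = 0.131). The fry test passed 4 lists that camera did not, namely hypoxia response, vacuolar ATPase, drug transporters, and blood and immune cell markers. In the authors' deposited table, 2687 genes had an adjusted p under 0.05, 1258 higher and 1429 lower, and 339 of them changed at least 2-fold, 113 higher and 226 lower. Among genes tested here, 2630 were called in the authors' deposited table, and 2612 of these (99.3%) were also called by limma-trend, all of them in the same direction. Of the genes named here as changed, 23 were not past the threshold in the authors' deposited table, with adjusted p from 0.0515 to 0.188. They include ATP5F1C, CEACAM6 and PLAUR. For the others, the settings listed above with lost calls leave out the authors' test. Another 1285 genes were called here alone and 18 in the authors' deposited table alone. Both sets of calls come from the same libraries, so their overlap is no independent evidence.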

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

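TMM scaling, the authors' own test and the omission of both libraries nearest the other group were added after the data were seen. No named gene or list changed its direction in a call under any setting. With library totals, TMM scaling, no filter, the stricter filter, limma-voom and a pseudocount of 0.1, the count of changed genes lay between 3697 and 3993, against 3897 as reported, and 11 or 12 lists passed. Genes with at least a 2-fold change numbered 310 with the stricter filter (85 higher, 225 lower) and 537 with no filter (217 higher, 320 lower), against 410 (136 higher, 274 lower) as reported. Library totals moved the share of higher genes among those changed from 48.4% to 58.0%, with 2315 higher and 1678 lower, and moved the median log2 fold change of all genes from 0.0009 to 0.0352. The authors' deposited test gave 2687 changed genes, 339 of them at least 2-fold. When single libraries were left out, the counts ran from 2118 to 4732 changed genes, from 251 to 622 genes with at least a 2-fold change, from 10 to 12 lists and from 1993 to 2610 genes shared with the authors' calls. Fewer samples enter those fits, and losing a library nearest the other group raised the number of genes with at least a 2-fold change, to 491 without pH 7.4 replicate 2 and 622 without pH 6.4 replicate 1. Without both, 4997 genes changed, 727 of them at least 2-fold, and 13 lists passed, with the hypoxia, mitotic and interferon lists gained and MYC targets lost. Because these libraries were picked for lying nearest the other group, the gains are no added evidence. With an estimated correlation, 0 lists passed camera, where the smallest adjusted p was 0.585, and 2 lists, the ATF4 list and fatty acid synthesis, had an unadjusted p under 0.05. At an authors' adjusted p under 0.01, 1625 genes were shared in place of 2612, since fewer genes enter the comparison.

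Whether replicate numbers pair the libraries was not tested, and pairing in part stays open. The correlations were 0.314, 0.220 and -0.042 between the deviations of same-numbered libraries and from -0.294 to 0.116 between others. Replicates 1 and 2 of each group correlated best with their own number. The pH 7.4 replicate 3 library correlated best with pH 6.4 replicate 2, at 0.070, so not every library correlated best with its own number. The replicate block gave 4843 changed genes, 463 with at least a 2-fold change, 13 lists and 2623 genes shared with the authors' calls. It kept 3890 of the calls made without the block. With the block, CDH1 (adjusted p = 1.04e-10), CA12 (adjusted p = 0.0391), the hypoxia list (adjusted p = 0.0368) and the interferon list (adjusted p = 0.0290) passed, and no other named gene or list changed its call.

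Over all settings, the 20 genes with the largest changes were past the threshold in 274 of the refits and missed it in 26. The other called genes that the naming rule took or that were singled out were past it in 1872 refits and missed it in 164. Such genes not called as reported stayed so in 277 and passed in 8. Of the 11 lists, 9 passed under every setting other than the estimated correlation, and DNA replication and MYC targets did not. The planned count models were not run, and the recovered reads were tested with limma-trend and limma-voom only. Size factor scaling is the scaling used throughout. Depth limits the genes below 10 reads, which were not tested. The 124 genes whose reads the search did not settle have no error estimate here.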

Other observations

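The KEGG pathway tests, the list of LXR targets, the test for cycling cells, the test of ATF4 genes in pH 6.4 replicate 1 and the choice of the genes in this opening were made after results were seen. Of 298 KEGG pathways with 15 to 300 tested genes, as annotated in the authors' table, 4 passed camera with its preset correlation, all lower at pH 6.4, and with an estimated correlation their adjusted p was 0.935. Systemic lupus erythematosus (41 of 78 genes lower, 4 higher, adjusted p = 1.01e-08), alcoholism (50 of 133 lower, 9 higher, adjusted p = 0.000417) and neutrophil extracellular trap formation (47 of 116 lower, 9 higher, adjusted p = 0.000654) are pathways in which KEGG includes many histone genes. In the pathway named ribosome, 37 of 116 genes were lower and 2 higher (adjusted p = 0.00851). Among the most abundant genes, the authors' deposited table gives a log2 fold change of -1.24 for EREG, which encodes the growth factor epiregulin, and of -1.03 for CDH17, an intestinal cadherin. It gives 0.64 for MSN, which encodes moesin, and 0.41 for CD44, a hyaluronan receptor. SLC38A2, an amino acid carrier regulated by ATF4, had a log2 fold change of -0.47 in the authors' deposited table, and IARS1, the isoleucyl-tRNA synthetase, one of -0.46.

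ABCA1, ABCG1, SREBF1 and SCD, all lower at pH 6.4, are known targets of the sterol-sensing LXR receptors. A candidate explanation is lower LXR activity in acid medium, which would lower other LXR targets too. Of 9 further genes listed as targets, 4 were lower and 0 higher (camera p = 0.0245, or p = 0.263 with an estimated correlation). Their median log2 fold change of -0.24 was that of NR1H2, which encodes an LXR receptor itself and may not be a target. APOE and APOC1, which did not pass, had few reads. The 4 lower genes were MYLIP (log2 fold change -0.81, adjusted p = 0.0480), LPCAT3 (-0.89), NR1H3 (-0.78) and SMPDL3A (-0.44, adjusted p = 0.0360). The hypothesis was found and tested in the same libraries, SREBF1 and SCD answer to other regulators as well, and sterol levels were not measured here.

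The fall of replication-dependent histone and cytosolic ribosomal protein transcripts might reflect gene length, since log2 fold change rose weakly with length across genes (Spearman's rho = 0.112, with genes not being independent replicates). Of 10000 random lists matched on length, 0.04% had a median at or below that of the histone list. For the ribosomal protein list the share was 0.94%. Taken as they stand, these shares argue against length as the whole cause of either fall. They treat genes as independent, and members of a list that vary together would make them too small. Fewer cycling cells would lower replication and mitotic genes as well, but these 51 genes had a median log2 fold change of 0.0886 (95% interval 0.0390 to 0.1316 from resampling of the genes). This interval takes the genes as independent and leaves out the spread between libraries. Arrest within the cycle, altered histone transcript stability and a change in the yield of RNA without a poly(A) tail were not tested. The difference in pH is what the design offers as a biological explanation, and it stays open beside these.

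The libraries pH 7.4 replicate 2 and pH 6.4 replicate 1 lay nearest the other group. With all libraries thinned to the depth of the shallowest, about 21600000 reads, they kept 101.5% and 100.4% of their positions between the groups, which argues against sequencing depth. In pH 6.4 replicate 1, mixed RNA would put the ATF4 genes near 0.612, the median position of genes called without this library. The median of the ATF4 genes was 1.031 (22 genes, 95% interval 0.960 to 1.086 from resampling of the genes), which argues against mixing as the whole cause. Of all tested genes, 3 lay below what such a share of pH 7.4 RNA would bring by itself (Poisson p under 1e-06, against 24 and 10 genes in pH 6.4 replicates 2 and 3). The Poisson p covers counting error alone, and replicates differed by more than that, so these 3 genes add little. In pH 7.4 replicate 2 the medians of the ATF4, histone, mitochondrial and epithelial lists spanned 0.650 (permutation p = 2e-05), but the bound set for that test was wrong, because they spanned from 0.379 to 1.32 in the other libraries too, all with a permutation p under 0.05. For this library, mixing and a difference between cultures cannot be told apart, since the lists spanned more (1.32) in pH 7.4 replicate 1, which lies away from the other group, and 0 genes lay clearly below what mixing would bring, as in the other pH 7.4 libraries.

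The 6 libraries can be divided into groups of 3 in 10 ways, which is too few for a share under 0.05. The real division gave 3897 changed genes, 410 with at least a 2-fold change and 11 lists, and 1 division of the 10, the real one, gave results that large. The highest of the other divisions was 0 genes, 0 genes with at least a 2-fold change and 9 lists. Each of the other divisions put libraries of both pH values in each group, so the pH difference entered the spread within groups. Their counts of genes therefore do not show what chance alone gives. Every other division also passed lists, from 2 to 9.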
